A study of Caenorhabditis elegans with 123 samples.

How the data were processed

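Gene expression was measured in staged pools of C. elegans embryos with Affymetrix C. elegans arrays, 34 of N2, 28 of mex-3(zu155); skn-1(RNAi), 27 of pie-1(zu154) and 34 of pie-1(zu154); pal-1(RNAi) embryos. The text calls the double genotypes mex-3/skn-1 and pie-1/pal-1. Time in minutes after the 4-cell stage and genotype were taken from the labels, which name 10 time points and so 40 groups of 2 to 4 arrays.

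The deposited table holds log2 values made by the authors, 1 value per probe set and array, from 1.79 to 12.72. The log2 scale was read from that range, and the labels do not state it. How probes were summarised, how background was treated and how arrays were made comparable is not given in the sources used here. Array medians lay between 3.24 and 3.41, and the number of arrays limits the precision of every value. Of 22625 probe sets 77 controls were left out and 22548 tested. The platform's probe table gave 1 gene symbol for 20766 probe sets, several for 887 and none for 895, and 20701 were found in the RefSeq gene table by their gene number. The tested probe sets stand for 17118 genes, of which 2981 have several probe sets. No genome came with the series, so no coordinates are given. Array description files were read for 97 arrays, and 26 pie-1 arrays have none. They gave a scan day for 96 arrays (9 days), a chip lot (4 lots), a number of embryos from 20 to 75 for 14 arrays, a rehybridisation note for 5 N2 arrays and, for 2 arrays, a time that differs from the label. Labelled times were kept. Every scan day lies within 1 genotype, and the N2 chip lot is shared with 1 pie-1 array only.

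A linear model with a mean for each of the 40 groups was fitted to the deposited values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a constant prior variance, 83 residual degrees of freedom, prior df 4.8). The early window is the unweighted mean of the groups at 0, 23 and 41 min and the late window that of 101, 122, 143 and 186 min. Contrasts set late against early N2, each mutant against N2 in either window, pie-1/pal-1 against pie-1 and mex-3/skn-1 against pie-1/pal-1 in the late window, and the late minus early change of each mutant against that of N2. Each time point was also compared singly, and an F test was run over the N2 times. All p-values of single probe sets are those of limma's moderated test, adjusted by Benjamini and Hochberg over all probe sets of a contrast. A probe set was called, and said to rise or fall or to be higher or lower, at an adjusted p under 0.05 and a change of at least 2-fold. Values are log2 differences ± SE from the fit unless SD is stated.

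The windows, contrasts, thresholds, gene lists, rule for naming genes and first set of alternatives were fixed before the data were examined. For each late contrast and the N2 contrast the rule names the 8 called probe sets with the largest rise and the 8 with the largest fall that have 1 symbol and the same sign at each time point. For the early windows and the interactions it names 5 and 5. It adds up to 4 members of each discussed list with the smallest adjusted p, and the 4 targeted genes. Where a gene has several probe sets, the brightest stands for it and disagreements are stated.

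Gene lists were written from general knowledge and tested with camera (preset correlation 0.01), again with the correlation estimated for each list, and with fry, over 216 list tests adjusted together. They cover genes downstream of PAL-1 (13 genes), body muscle (27), epidermis (23), endoderm (18), the EMS and MS lineages (11), pharynx (15), neurons (26), Hox genes (7), Notch signalling in the AB lineage (8), early zygotic genes (44), sdz genes (32), germline and P granules (28), maternal genes of the egg-to-embryo transition (29), cell division (30), ribosomal proteins (62), collagens and cuticle (160), stress (14), and adult soma and sperm (42). The first of these was partly chosen by the study on these samples, and so is no independent evidence of its direction in any contrast. It shares 3 genes (hlh-1, unc-120, hnd-1) with body muscle and 4 (elt-1, elt-3, nhr-25, lin-26) with epidermis, pha-4 is in the lists of pharynx and of the EMS and MS lineages, and all sdz genes are among the early zygotic genes. Camera compares a list with the other genes, and fry tests whether its members move on balance 1 way. Of the 216 tests 77 passed in camera and 23 passed with an estimated correlation too. Genes of a list are not independent replicates.

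The steps were tested on simulated data for 8 comparisons with 200 of 22548 probe sets changed. At a log2 change of 1.5 at least 98.5% were recovered and at 2 and 3 all of them, with at most 1 false call. The simulated noise was independent between arrays, with the spread of each probe set and no batch, shift or outlying array. The simulation checks the steps and gives no rate of false calls for the real arrays.

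The alternatives planned were quantile normalization, centring each array on its median, leaving out dim probe sets, fitting only the groups of a contrast, array weights, a trended robust prior, no fold minimum, an adjusted p of 0.01, replicate blocks, narrow windows, the late window without 186 min, a batch from the description files (scan day) as a random block, and leaving out each array. Alternatives chosen after seeing the data were scan day as a fixed block, chip lot as a block, the arrays of chip lot 2 alone, centring on probe sets with a mean of at least 5, the GAPDH 3' minus 5' difference as a term, leaving out arrays far from their group, rehybridised arrays or the 2 arrays with conflicting notes, and 3 settings that follow the naming of N2 replicates. Other scalings of the counts over time points were also chosen after seeing the data. Tables and figures were made with the data.table package, version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.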

Results

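Transcript levels were measured on Affymetrix arrays in small pools of Caenorhabditis elegans embryos of 4 genotypes at 10 time points, 0, 23, 41, 53, 66, 83, 101, 122, 143 and 186 min after the 4-cell stage at 22 °C. N2 is the standard wild-type strain. The pie-1(zu154) embryos lack function of PIE-1, a zinc finger protein that keeps transcription off in the germline blastomeres. The pie-1(zu154); pal-1(RNAi) embryos, called pie-1/pal-1 here, also received RNA interference against pal-1. This caudal-type homeobox gene specifies the posterior C and D lineages. The mex-3(zu155); skn-1(RNAi) embryos, called mex-3/skn-1 here, lack MEX-3, an RNA-binding protein that represses pal-1 translation in anterior cells. They also received RNA interference against skn-1, a transcription factor that specifies the EMS blastomere, the founder of endoderm and of much of the mesoderm. N2 had 34 arrays, mex-3/skn-1 28, pie-1 27 and pie-1/pal-1 34, with 2 to 4 arrays per genotype and time point. The early window covered 0 to 41 min (10 N2, 8 mex-3/skn-1, 8 pie-1 and 11 pie-1/pal-1 arrays) and the late window 101 to 186 min (12, 12, 12 and 13 arrays). Array medians lay between 3.24 and 3.41 on the log2 scale. The number of arrays limits the precision of every value. The labels do not state whether replicates came from separate collections of embryos, so p-values measure the spread between these arrays, which may be technical. Changes below are differences of log2 expression between windows or genotypes, with limma's standard error (SE).

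The targeted genes were examined first. In N2 the pie-1 transcript averaged 7.69 ± 0.40 (SD, n = 10) in the early window and 4.48 ± 0.54 (n = 12) in the late window. In pie-1 embryos it was near the floor, at 3.52 ± 0.21 (n = 8) early and 3.48 ± 0.19 (n = 12) late. In pie-1/pal-1 embryos it was 3.45 ± 0.18 (n = 11) early and 3.44 ± 0.16 (n = 13) late. The early difference from N2 was -4.16 ± 0.14 in pie-1 (adjusted p = 8.06e-43) and -4.22 ± 0.13 in pie-1/pal-1 (adjusted p = 2.16e-46). The mex-3 transcript averaged 8.03 ± 0.77 (n = 10) in early N2 and 3.54 ± 0.28 (n = 8) in early mex-3/skn-1 embryos, a difference of -4.42 ± 0.35 (adjusted p = 2.34e-18), and the other mex-3 probe set gave -5.17. It was also lower in the other mutants early, by -1.29 ± 0.35 in pie-1 and -1.47 ± 0.32 in pie-1/pal-1, although the other probe set gave -0.87 and -0.83, below the 2-fold minimum.

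The pal-1 transcript did not follow the RNAi label in every array. In the early window its median was 5.55 in pie-1/pal-1 arrays, with a range from 4.95 to 12.21 (n = 11), and 8.19 in pie-1 arrays (range 7.53 to 9.08, n = 8). The early difference of pie-1/pal-1 from N2 was -1.12 ± 0.49 and missed the threshold (adjusted p = 0.063), whereas the other 2 pal-1 probe sets were called at -2.18 and -1.71. Late pal-1 in pie-1/pal-1 arrays ranged from 5.36 to 10.32 (n = 13), with a median of 6.39 against 6.32 in late pie-1 arrays (n = 12). By the brightest probe set, the 15 pie-1/pal-1 arrays of 1 scan day, replicates 3 and 4, measured 5.32 to 6.79 over all times. All pie-1/pal-1 values above 6.79 came from the 19 arrays of the other scan day, which ranged from 4.95 to 12.21. The pie-1 array at 53 min, replicate 3, which carries no RNAi label, measured 12.49, and 10.65 and 11.70 by the other 2 probe sets. Late pal-1 in pie-1 arrays was -0.71 ± 0.46 against N2 and was not called (adjusted p = 0.214), whereas the other 2 probe sets were called lower at -1.70 and -1.49. A probe can also detect the injected double-stranded RNA. In mex-3/skn-1 embryos late pal-1 was 1.62 ± 0.47 above N2 (adjusted p = 0.00396), and its other 2 probe sets gave 0.97 and 0.59, neither called. Early pal-1 measured 0.60 there (not called), against -1.33 (called) and -0.87 (not called) by the other 2. In narrow windows late pal-1 measured 1.25 and lost its call. The skn-1 transcript was dim, with window means of its brightest probe set between 3.6 and 4.38. In early mex-3/skn-1 embryos that probe set measured -0.45 ± 0.13 against N2 (adjusted p = 0.00351, under the fold minimum). Another was called lower at -1.09 (adjusted p = 2.73e-10), with 2.69 at 0 min against 4.20 in N2, 4.70 in pie-1 and 4.88 in pie-1/pal-1 embryos, and the remaining one gave -0.19. The median change of probe sets with a mean of at least 5 was -0.516 in that comparison. In the late window none of the 3 was called, with values of 0.06 to 0.07.

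**Figure D1:**
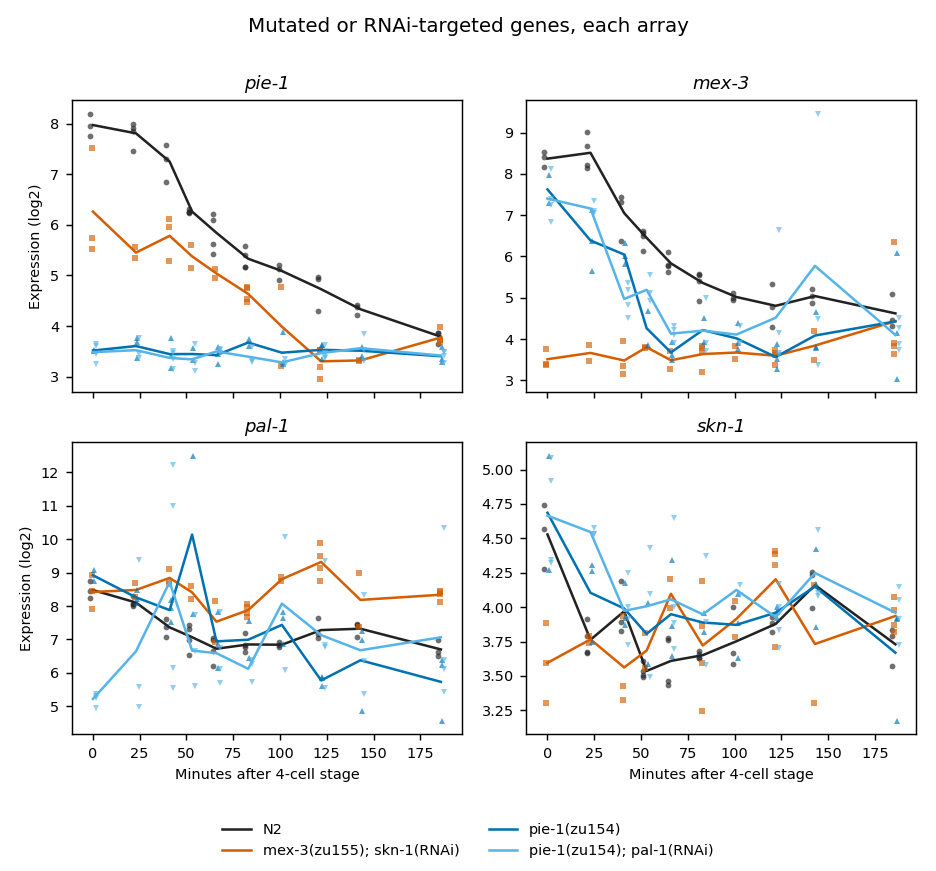
Expression (log2) of pie-1, mex-3, pal-1 and skn-1 against minutes after the 4-cell stage, with a point per array and a line through the group means of each genotype. Early pie-1 averaged 7.69 in N2 and 3.52 in pie-1 embryos, and early mex-3 averaged 3.54 in mex-3/skn-1 embryos. The pal-1 values of pie-1/pal-1 arrays scatter from 4.95 to 12.21 in the early window.

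Which transcripts change as wild-type development proceeds was asked by setting late against early N2 arrays. Transcripts deposited in the oocyte fell: mex-6, a zinc finger gene of anterior-posterior polarity, by -4.57 ± 0.21, its paralog mex-5 by -3.68 ± 0.17, the Y-box gene cey-2 by -4.66 ± 0.24, and the small heat shock protein gene sip-1 by -4.85 ± 0.25. F14H3.6 fell by 5.20, and era-1, T21C9.13, Y52B11A.8 and trcs-1 fell by values between 4.57 and 4.81. The largest rises were those of arrd-1, with an arrestin domain (5.59 ± 0.18), the linker histone gene his-24 (5.59 ± 0.17) and hmg-11 (5.49 ± 0.18). Next came the C-type lectin gene clec-196 (5.06), the laminin alpha gene epi-1 (5.06 ± 0.22) and clec-266 (5.03), another such lectin gene. T19B10.2 (5.00) and the kynureninase gene kynu-1 (4.86) followed. In all, 3368 of 22548 probe sets were called, 1511 higher and 1857 lower late, for 1187 and 1491 genes. The largest adjusted p among these named genes was 1.61e-31.

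By group, 19 of 28 germline and P granule genes fell and none of the other members rose past the threshold, among them gld-3 (-3.67 ± 0.16), the meiotic axis gene him-3 (-2.98 ± 0.13), meg-1 (-3.02 ± 0.16) and pgl-1 (-2.55 ± 0.14). Another gld-3 probe set near the floor gave -0.54. Of 29 maternal genes of the egg-to-embryo transition, 22 fell and the caveolin gene cav-1 rose by 3.52 ± 0.11. Of 26 neuronal genes 11 rose, among them the Otx homeobox gene ceh-36 (3.53 ± 0.13), the achaete-scute homolog hlh-14 (2.88 ± 0.18), the atonal homolog lin-32 (1.98 ± 0.14) and the forkhead gene unc-130 (1.83 ± 0.10). Of 13 genes placed downstream of PAL-1, 9 rose. That list was partly chosen by the study on these samples and is no independent evidence of its direction. The GATA factor gene elt-1 of the epidermis (3.42 ± 0.23), the MyoD homolog hlh-1 (2.08 ± 0.14), the Hand gene hnd-1 (3.01 ± 0.22) and the MADS-box muscle regulator unc-120 (2.40 ± 0.17) led. These 4 list results held in camera with the preset and with an estimated correlation (adjusted p = 0.00209, 0.00937, 0.00192 and 0.00738 with an estimated correlation). Counts of members adjusted over the list alone were the same as those over all genes in every list of this comparison.

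The next 5 lists did not pass with an estimated correlation. Of 62 ribosomal protein genes 52 rose (median change 1.61), led by rps-16 (2.52 ± 0.15) and rpl-19 (2.14 ± 0.12), with adjusted p = 3.10e-27 in camera and adjusted p = 0.0922 with an estimated correlation. The epidermal list had 6 of 23 members higher, with noah-1 at 3.63 ± 0.21 and the collagen sqt-3 at 1.99 ± 0.13 (adjusted p = 0.0562 with an estimated correlation). The endoderm list had 4 of 18 higher. These were the GATA factor genes elt-7 (1.75 ± 0.12), elt-2 (1.59 ± 0.12) and end-1 (1.55 ± 0.16) and the homeobox gene dve-1 (3.04 ± 0.16). The list had adjusted p = 0.0767 with an estimated correlation, and its call ended under quantile normalization (0.0735). Of 11 genes of the EMS and MS lineages 3 rose and 1 fell. They were pha-4, the FoxA gene of pharyngeal identity, by 3.94 ± 0.15, the MS homeobox gene ceh-51 by 2.22 ± 0.16, tps-2 by 1.71 ± 0.16, and sdz-38 by -1.53 ± 0.17 (adjusted p = 0.0922 with an estimated correlation). Of 30 cell division genes 5 rose and 6 fell, the B-type cyclins cyb-2.2 (-3.85 ± 0.17) and cyb-2.1 (-3.68 ± 0.19) and the phosphatase cdc-25.1 (-2.81 ± 0.15) falling while cdc-25.2 rose by 2.18 ± 0.17 (camera adjusted p = 0.996).

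N2 arrays did not form a single even series. N2 replicates carry letters at 0, 41, 101 and 143 min, numbers at 23, 53, 83, 122 and 186 min, and both at 66 min. The level of 158 probe sets alternated with that naming by at least 0.5. At lettered times 35 of them were lower and the rest higher. By the same rule 3 probe sets alternated in mex-3/skn-1, 0 in pie-1 and 2 in pie-1/pal-1 embryos. In N2 the germ granule helicase gene cgh-1 measured 8.15, 6.47, 8.23 and 5.61 at 0, 23, 41 and 53 min, and the Hsc70 gene hsp-1 measured 7.55, 5.94, 6.70 and 5.47. These genes were singled out after their values were seen. Of the 158 probe sets, 65 were among the 3368 called late against early in N2. N2 scan day nearly followed time as well: 1 day held 9 early arrays, another 10 late arrays, and on only 1 day, with 1 early and 2 late arrays, were both windows scanned. With scan day as a fixed block, a setting chosen after seeing the data, 3126 probe sets were called.

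The mex-3/skn-1 embryos, in which many blastomeres are known to take fates like those of C, were compared with N2 to ask which transcripts change when skn-1 and mex-3 activity is missing. In the late window the lower genes included pha-4 (-3.88 ± 0.15), the Distal-less homolog ceh-43 (-4.35 ± 0.15), ceh-36 (-3.60 ± 0.13) and ceh-51 (-2.32 ± 0.16). Of the 15 pharynx genes pha-4 alone was called (camera adjusted p = 0.860). The mutant levels of such genes lay near the floor, which limits how large a fall can be measured. T19B10.2 was lower by -4.89 ± 0.18, the DNase II gene nuc-1 by -4.36 ± 0.18, C29F7.2 by -4.22 ± 0.15, T03F6.3 by -3.86 ± 0.15, the glucuronosyltransferase gene ugt-23 by -3.76 ± 0.18 and the ribosomal RNA gene rrn-3.1 by -3.65 ± 0.40. The other 4 rrn-3.1 probe sets gave -4.35, -3.11, -2.48 and -0.87, and rrn-3.1 was lower in every mutant in both windows. Higher were cpg-3, a chondroitin proteoglycan gene of the eggshell (3.14 ± 0.14), the Wnt gene cwn-1 (1.73 ± 0.47), and the Scratch-type zinc finger gene scrt-1 (1.61 ± 0.14). So were pal-1, T22B7.3 (1.65 ± 0.14), the muscle kettin gene ketn-1 (1.53 ± 0.16), the calponin gene cpn-1 (1.52 ± 0.18) and F45D3.1 (1.42 ± 0.19). The second probe sets of T22B7.3, ketn-1 and cpn-1 gave 0.68, 0.37 and 0.19 and were not called. In all 1413 probe sets were called, 34 higher and 1379 lower.

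All 4 called members of the endoderm list were lower, dve-1 by -2.33 ± 0.16, end-1 by -1.77 ± 0.15, elt-7 by -1.58 ± 0.12 and elt-2 by -1.34 ± 0.11. The same held for 4 of 11 EMS and MS genes, with tps-2 at -1.62 ± 0.15 and sdz-26 at -1.27 ± 0.21 (-0.93 under quantile normalization) beside pha-4 and ceh-51. It held for 8 of 26 neuronal genes, with unc-130 at -1.83 ± 0.10, lin-32 at -1.77 ± 0.13 and ceh-37 at -1.73 ± 0.13. These 3 lists held with an estimated correlation (adjusted p = 0.0230, 0.0221 and 0.00738). Over the lettered N2 times, a setting chosen after seeing the data, the endoderm call ended (0.111). Of 30 cell division genes 15 were lower, including the ribonucleotide reductase genes rnr-1 (-2.88 ± 0.17) and rnr-2 (-1.80 ± 0.15), the PCNA gene pcn-1 (-1.96 ± 0.20) and the licensing gene cdt-1 (-1.41 ± 0.13), with adjusted p = 0.0615 with an estimated correlation. The anterior Hox gene ceh-13 was lower by -2.62 ± 0.17. Of the 13 PAL-1 downstream genes, partly chosen by the study on these samples, scrt-1 and cwn-1 were higher, whereas elt-1 measured -0.76 ± 0.23 and nhr-25 0.56 ± 0.14, under the fold minimum (camera adjusted p = 0.149). Quantile normalization brought that list past the threshold (0.000281), as did the time points with numbered N2 arrays (0.000160), whereas those with lettered N2 arrays gave 0.973. None of the 27 body muscle genes was called by limma, although 7 had an adjusted p under 0.05 and missed only the fold minimum, with values from -0.80 to 0.53.

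The GAPDH 3' minus 5' difference, a sign of RNA integrity or amplification, averaged 1.48 ± 0.39 (SD, n = 28) in mex-3/skn-1 against 0.77 ± 0.27 (n = 34) in N2 arrays, the 75th percentile 4.09 ± 0.13 against 4.42 ± 0.10. The median change of probe sets with a mean of at least 5 was -0.505. Of the late calls 26.9% were higher after quantile normalization (198 higher, 538 lower) and 59.6% after centring each array on those brighter probe sets (490 higher, 332 lower), where the call of elt-2 ended (-0.74). The count itself was 736 and 822 under these scalings. In settings chosen after seeing the data it was 851 with the GAPDH difference as a term, 934 without 9 arrays far from their groups, 780 over the numbered and 2487 over the lettered N2 times. Leaving out those 9 arrays also took 143 min out of the late window. The mutant's scan days and chip lots held no N2 array, so batch and genotype cannot be told apart.

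**Figure D2:**
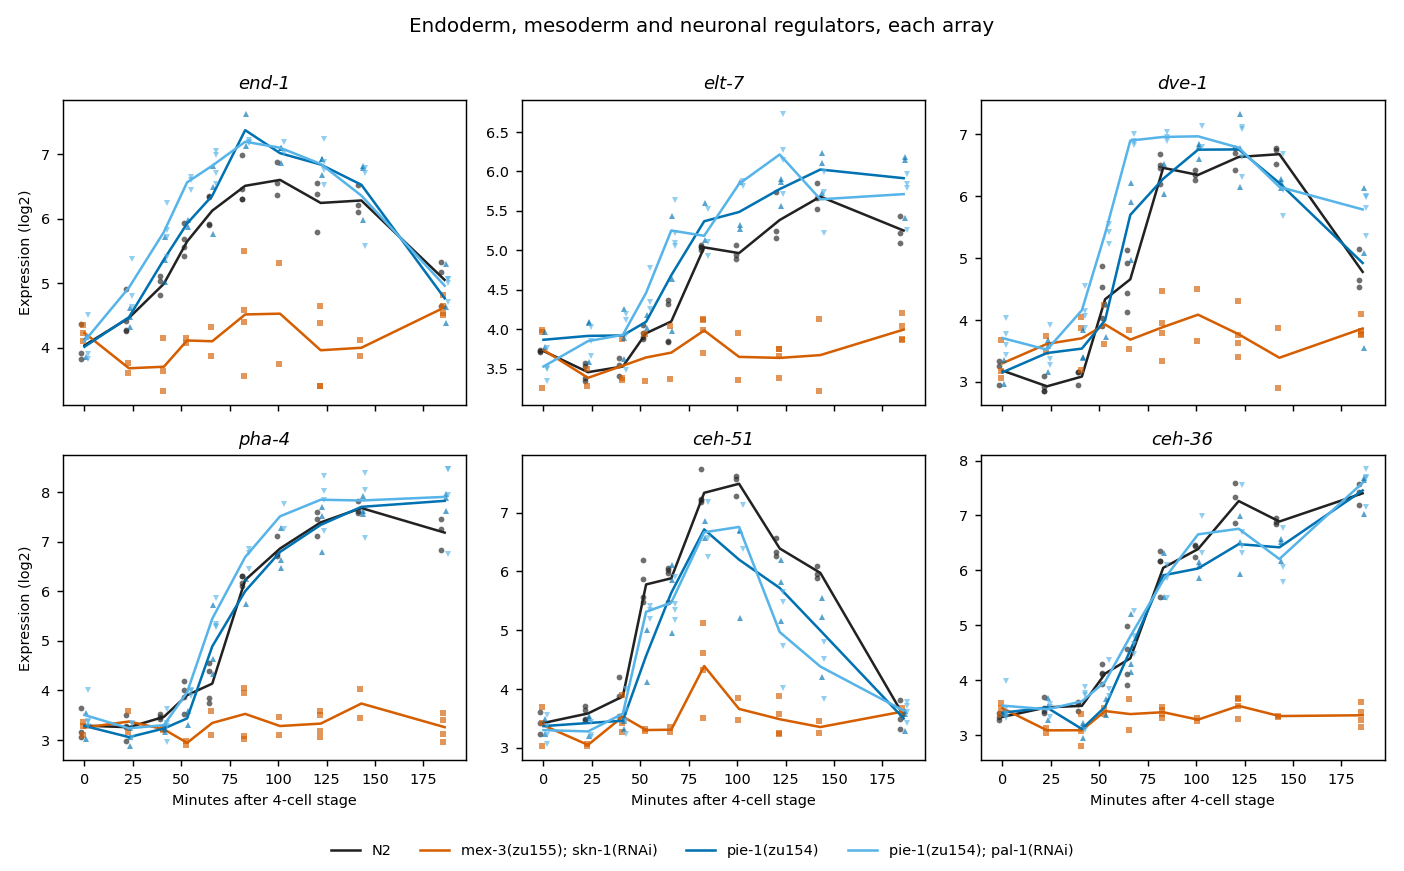
Mean expression (log2) of end-1, elt-7, dve-1, pha-4, ceh-51 and ceh-36 against minutes after the 4-cell stage, with a line per genotype, points for arrays. From 101 min on pha-4 stood between 6.79 and 7.91 in N2, pie-1 and pie-1/pal-1 embryos and between 3.26 and 3.74 in mex-3/skn-1 embryos.

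A comparison free of N2 arrays set mex-3/skn-1 against pie-1/pal-1 embryos, the genotypes that differ most in known PAL-1 activity. Here 9 of the 13 PAL-1 downstream genes were higher in mex-3/skn-1 embryos: scrt-1 by 2.65 ± 0.14, tbx-9, a T-box gene, by 2.09 ± 0.17, hnd-1 by 1.94 ± 0.21 and hlh-1 by 1.87 ± 0.14. The list was partly chosen by the study on these samples and is no independent evidence of this difference. It had adjusted p = 9.91e-21 in camera and adjusted p = 3.35e-06 with an estimated correlation. The count was also 9 adjusted over the list alone. The muscle regulators hlh-1, hnd-1 and unc-120 (1.52 ± 0.17) were also the 3 called members of the body muscle list (adjusted p = 0.257 with an estimated correlation). Higher epidermal genes were elt-1 (1.37 ± 0.23), sqt-3 (1.3 ± 0.13), nhr-25 (1.24 ± 0.14) and lin-26 (1.05 ± 0.14), and the epidermal list itself missed the threshold (camera adjusted p = 0.117). The second probe sets of nhr-25 and lin-26 gave 0.36 and 0.60, and lin-26 measured 0.84 without the mex-3/skn-1 array at 101 min, replicate 4, and 0.85 without that at 143 min, replicate 2. Also higher were spp-10, with saposin domains (6.49 ± 0.16, though 0.13 by another probe set near the floor), the lysine catabolism gene aass-1 (5.19 ± 0.15) and T22B7.3 (4.72 ± 0.14). So were cwn-1 (4.16 ± 0.47), mfsc-1 (3.82 ± 0.14), the aquaporin gene aqp-2 (3.66 ± 0.17), and the eggshell genes cpg-3 (3.38 ± 0.14) and cpg-2 (3.27 ± 0.26).

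Lower in mex-3/skn-1 than in pie-1/pal-1 embryos were pha-4 (-4.37 ± 0.15), T19B10.2 (-5.20 ± 0.18), nuc-1 (-5.07 ± 0.18), C29F7.2 (-4.55 ± 0.15), the glyoxylate cycle gene icl-1 (-4.55 ± 0.19), ugt-23 (-4.50 ± 0.18), the acid sphingomyelinase gene asm-1 (-4.14 ± 0.15) and the acid phosphatase gene acp-2 (-4.13 ± 0.16). The endoderm list had 4 members lower, elt-7 (-2.12 ± 0.12), dve-1 (-2.64 ± 0.16), end-1 (-2.04 ± 0.15) and elt-2 (-1.22 ± 0.11, and -0.87 after centring on brighter probe sets), with adjusted p = 0.00213 with an estimated correlation. The EMS and MS list had 3 lower, tps-2 (-1.57 ± 0.15) and ceh-51 (-1.40 ± 0.16) beside pha-4 (adjusted p = 0.00937 with an estimated correlation). The neuronal list had 7 lower, among them ceh-36 (-3.42 ± 0.13), ztf-11 (-1.72 ± 0.16), ceh-37 (-1.36 ± 0.13) and unc-44 (-1.93 ± 0.15, with 3 other probe sets from -3.04 to -2.01 and 5 from -0.14 to 0.06), with adjusted p = 0.000344 with an estimated correlation. Of 29 maternal genes 6 were higher, pos-1 by 2.64 ± 0.22 and puf-11 by 1.25 ± 0.18 beside cpg-2 (adjusted p = 0.141 with an estimated correlation). The difference in puf-11 was 0.92 without the mex-3/skn-1 array at 101 min, replicate 4. In all 665 probe sets were called, 144 higher and 521 lower. In settings chosen after seeing the data, 655 were called with chip lot as a block, and 129 were higher and 725 lower within chip lot 2. That lot held 4 late mex-3/skn-1 arrays and 10 late pie-1/pal-1 arrays, of which 7 were at the times both genotypes share there, so 186 min did not enter. Within that lot sqt-3 measured -0.02, lin-26 0.61 and puf-11 0.54, and these calls and that of cwn-1 (3.37) ended. With chip lot as a block sqt-3 measured 0.93 and puf-11 0.96, under the fold minimum. The share of higher calls was 38.1% after quantile normalization and 52.6% after centring on brighter probe sets, whose median change was -0.277.

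**Figure D3:**
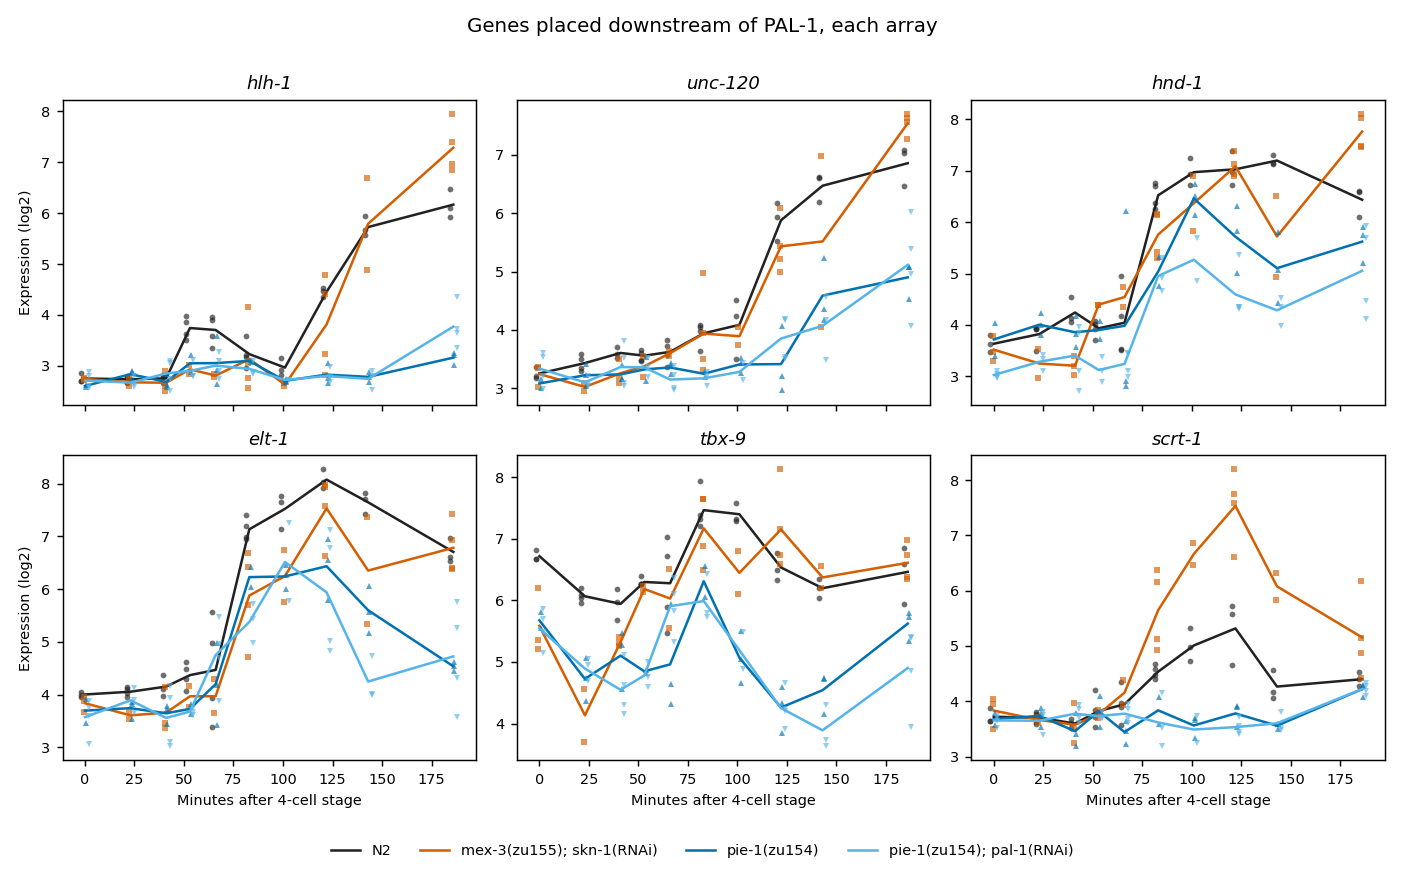
Mean expression (log2) of hlh-1, unc-120, hnd-1, elt-1, tbx-9 and scrt-1 against minutes after the 4-cell stage, with a line per genotype and points for arrays. At 186 min hlh-1 stood at 6.17 in N2, 7.28 in mex-3/skn-1, 3.16 in pie-1 and 3.77 in pie-1/pal-1 embryos.

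The pie-1 embryos were compared with N2 to see what the loss of PIE-1 changes. In the late window muscle and epidermal regulators downstream of PAL-1 were lower: hlh-1 by -1.96 ± 0.14, tbx-9 by -1.78 ± 0.17, unc-120 by -1.75 ± 0.17 and the epidermal zinc finger gene lin-26 by -1.14 ± 0.14. Of the 13 genes of that list, partly chosen by the study on these samples, 7 were lower (adjusted p = 1.76e-12 in camera and adjusted p = 0.000547 with an estimated correlation). The largest falls were those of spp-10 (-4.34 ± 0.16, with another probe set at 0.01), aass-1 (-3.74 ± 0.15), grif-1 (-3.42 ± 0.18), and the dihydropyrimidinase gene dhp-2 (-3.01 ± 0.15). Also lower were the ribosomal RNA gene rrn-3.1 (-3.01 ± 0.38), mfsc-1 (-2.74 ± 0.13), the glycogenin gene gyg-2 (-2.63 ± 0.20) and ule-3 (-2.49 ± 0.40). Of the other 4 rrn-3.1 probe sets 3 gave -3.93, -2.52 and -2.03 and 1 gave -0.72, not called, and the other ule-3 probe set gave -0.04. The level of pha-4 was 7.83 at 186 min (7.19 in N2). Over the late window no member of the pharynx list, which holds pha-4, lay more than 0.31 above N2. For ceh-51 the value was -0.75 ± 0.15, under the fold minimum. None of the 18 endoderm genes was called by limma, although 5 had an adjusted p under 0.05 and missed only the fold minimum, with elt-7 at 0.48 ± 0.12. In all 668 probe sets were called, 16 higher and 652 lower.

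Of 29 maternal genes 9 were lower, led by the Y-box gene cey-3 (-2.29 ± 0.22), cpg-2 (-2.22 ± 0.25), the zinc finger gene pos-1 (-2.01 ± 0.21) and the Pumilio gene puf-11 (-1.77 ± 0.18), with adjusted p = 0.0922 with an estimated correlation. Of 28 germline genes 3 were lower, the nanos homolog nos-2 (-1.85 ± 0.17), deps-1 (-1.70 ± 0.20) and the vasa homolog glh-1 (-1.0 ± 0.18), with adjusted p = 0.435 with an estimated correlation. The calls of glh-1 and of the list ended under quantile normalization (-0.61 and 0.0572). The epidermal list had 4 lower, sqt-3 by -1.87 ± 0.13 and elt-1 by -1.78 ± 0.22 among them (adjusted p = 0.175 with an estimated correlation), and the neuronal gene unc-130 was lower by -1.56 ± 0.09. The few higher genes were cest-26 (1.77 ± 0.27), the mitochondrially encoded COX2 (1.4 ± 0.29), ND4 (1.11 ± 0.25) and ND1 (1.11 ± 0.24), rab-11.1 (1.21 ± 0.24), zfp-3 (1.10 ± 0.18), nlp-31 (1.08 ± 0.21) and swsn-1 (1.06 ± 0.16). Their calls are weakly held. The other probe set of cest-26 gave 0.14, another of rab-11.1 gave -0.28, 3 of zfp-3 gave -0.39, -0.41 and -0.45, and the other of swsn-1 gave -0.20. Probe sets of COX1, COX3, CYTB and rab-11.1 were among those that alternate in N2. With the GAPDH difference as a term, rab-11.1 measured 0.81, ND4 0.79, ND1 0.73, zfp-3 0.80, nlp-31 0.91 and swsn-1 0.81.

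The GAPDH 3' minus 5' difference was 1.19 ± 0.38 (SD, n = 27) in pie-1 arrays, the 75th percentile 4.11 ± 0.09, and the median change of probe sets with a mean of at least 5 was -0.34. Of the late calls 24.8% were higher after quantile normalization (81 higher, 245 lower) and 36.9% after centring on those probe sets (115 higher, 197 lower), and hnd-1 (-1.18 ± 0.20) and lin-26 lost their calls under quantile normalization (-0.85 and -0.80). The count was 326 and 312 under these scalings and, in settings chosen after seeing the data, 341 with the GAPDH term and 1024 over the lettered N2 times.

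The pie-1/pal-1 embryos were compared with N2 in the same way. Again 7 of the 13 PAL-1 downstream genes, partly chosen by the study on these samples, were lower: hnd-1 by -2.11 ± 0.20, tbx-9 by -2.09 ± 0.17, hlh-1 by -1.82 ± 0.14 and unc-120 by -1.75 ± 0.17 (adjusted p = 4.14e-15 in camera and adjusted p = 0.000123 with an estimated correlation). Largest were the falls of spp-10 (-5.34 ± 0.16, with another probe set at 0.08), aass-1 (-4.05 ± 0.15), rrn-3.1 (-3.75 ± 0.38), grif-1 (-3.34 ± 0.18), ule-3 (-3.32 ± 0.40, with another probe set at 0.11), T22B7.3 (-3.07 ± 0.13), dhp-2 (-3.01 ± 0.15) and aqp-2 (-2.83 ± 0.17). Higher were ncam-1, a neural cell adhesion molecule homolog (2.00 ± 0.14, and 0.45 by another probe set), COX2 (1.76 ± 0.29), cest-26 (1.48 ± 0.27) and F07H5.13 (1.45 ± 0.22). So were rab-11.1 (1.36 ± 0.24, with another probe set at -0.18), C33D9.5 (1.36 ± 0.20, and 0.30 by another probe set), C10C5.5 (1.36 ± 0.13) and nlp-31 (1.34 ± 0.21). In all 526 probe sets were called, 61 higher and 465 lower.

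Maternal genes were lower for 10 of 29 members, with cey-3 at -2.51 ± 0.22, cpg-2 at -2.44 ± 0.25, pos-1 at -2.33 ± 0.21 and puf-11 at -1.59 ± 0.18 (adjusted p = 0.0748 with an estimated correlation). Germline genes nos-2 (-1.90 ± 0.17), deps-1 (-1.72 ± 0.20) and glh-1 (-1.16 ± 0.18) were lower (adjusted p = 0.423 with an estimated correlation). So were the epidermal genes elt-1 (-2.13 ± 0.22) and sqt-3 (-1.91 ± 0.13), whose list had adjusted p = 0.201 with an estimated correlation and lost its call under quantile normalization (0.0699). For pha-4 the value was 0.49 ± 0.14 and for elt-7 0.53 ± 0.12, both under the fold minimum. The GAPDH difference was 1.4 ± 0.30 (SD, n = 34), the 75th percentile 4.15 ± 0.12, and the median change of probe sets with a mean of at least 5 was -0.239. Of the late calls 34.4% were higher after quantile normalization (144 higher, 274 lower) and 42.5% after centring on those probe sets (169 higher, 229 lower). Leaving out 9 arrays far from their groups, a setting chosen after seeing the data that also took 143 min out of the late window, gave 343 calls. Others of that kind gave 245 with the GAPDH term and 818 over the lettered N2 times.

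What RNAi against pal-1 changes within pie-1 embryos was asked by comparing both genotypes. Over the late window pie-1/pal-1 arrays differed from pie-1 arrays in 9 of 22548 probe sets. At single times 295 were called at 41 min, 272 at 66 min, 69 at 122 min and 53 at 186 min, and 2 to 17 at each of the other times. At 41 min 3 of 4 pie-1/pal-1 arrays matched N2 at 66 min best, and all 3 pie-1 arrays matched N2 at 41 min. The pie-1 arrays at 66 min had root mean square residuals from 0.385 to 0.410, against a median of 0.251 over all arrays. No scan day or chip lot is known for 26 of the 27 pie-1 arrays, so batch and RNAi cannot be told apart here. Higher with the RNAi were eppl-1 (1.27 ± 0.14, adjusted p = 1.09e-10), ncam-1 (1.15 ± 0.14), EEED8.2 (1.05 ± 0.12), mtre-1 (1.01 ± 0.16), the talin gene tln-1 (1.01 ± 0.15) and the Argonaute gene alg-1 (1.0 ± 0.17). Lower were T22B7.3 (-1.14 ± 0.13, adjusted p = 1.77e-09) and sdz-27 (-1.10 ± 0.19). None of the 13 PAL-1 downstream genes was called by limma, although 3 had an unadjusted p under 0.05: hnd-1 at -0.93 ± 0.20 (adjusted p = 0.00425, under the fold minimum), elt-3 at 0.20 ± 0.10 and lin-26 at 0.28 ± 0.14. The 95% intervals of hnd-1 (-1.33 to -0.52) and cwn-1 (-1.53 to 0.28) include a fall of 2-fold. The other 11 lay between -0.79 and 0.67, among them -0.65 to 0.02 for tbx-9, -0.79 to 0.09 for elt-1, -0.13 to 0.41 for hlh-1 and -0.33 to 0.33 for unc-120, genes chosen after their values were seen. At 186 min hlh-1 in pie-1 embryos already lay near the floor, so a further fall there could hardly be measured. Whether low levels limit the other intervals was not examined. The list as a whole had camera adjusted p = 0.703. The neuronal list was shifted up (adjusted p = 0.00923 in camera, adjusted p = 0.0754 with an estimated correlation). Its members included egl-44 at 0.44 ± 0.09, snb-1 at 0.58 ± 0.13 and hlh-2 at 0.54 ± 0.12, all under the fold minimum, and quantile normalization ended that call (0.115).

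The pal-1 transcript itself measured 0.90 ± 0.46 higher in late pie-1/pal-1 than in late pie-1 arrays (adjusted p = 0.318). All late pie-1/pal-1 values above 6.79 came from arrays of 1 scan day. The calls of ncam-1, mtre-1, tln-1 and alg-1 ended under quantile normalization (0.99, 0.86, 0.91 and 0.88), where 3 probe sets were higher and 4 lower. Without the pie-1 array at 186 min, replicate 2, EEED8.2 measured 0.91 and alg-1 0.85, and leaving out single arrays ended the call of alg-1 for 10 arrays, of mtre-1 for 13 and of tln-1 for 11. The call of sdz-27 ended without the pie-1 array at 143 min, replicate 2. Other tln-1 probe sets gave values from -0.19 to 0.13, and the count ranged from 6 without the pie-1 array at 186 min, replicate 2, to 14 without the pie-1 array at 143 min, replicate 3.

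Before zygotic transcription dominates, early embryos mostly hold RNA from the mother, and that RNA falls as development proceeds, so the early window compares maternal RNA only as far as the embryos were of the same stage. Of the pie-1/pal-1 arrays at 41 min, 3 of 4 matched N2 at 66 min best. All 3 pie-1 arrays at 23 min matched N2 at 41 min best, as did 2 of 3 pie-1/pal-1 and 2 of 2 mex-3/skn-1 arrays. Of the 8 mutant arrays at 23 min 1 matched N2 at 23 min best, and of the 7 at 53 min 0 matched N2 at 53 min. Both are times with numbered N2 arrays, so these matches do not separate stage from the alternation of the N2 arrays. Among probe sets with 1 symbol, the largest early rises in mex-3/skn-1 embryos were those of the eggshell genes cpg-3 (5.62 ± 0.16) and cpg-2 (3.18 ± 0.29), the polo-like kinase gene plk-3 (3.21 ± 0.17), sqv-4, which makes a precursor of chondroitin (3.02 ± 0.17), and strl-1 (2.91 ± 0.20). The yolk receptor gene rme-2 was higher by 2.02 ± 0.19. At 0 min cpg-3 stood at 10.37 in mex-3/skn-1 embryos, 5.25 in N2, 3.85 in pie-1 and 4.02 in pie-1/pal-1 embryos. Of 29 maternal genes 5 were higher and 7 lower (camera adjusted p = 0.431), pie-1 among the latter at -1.85 ± 0.14. Of 28 germline genes 6 were lower and 1 higher, cgh-1 at -2.49 ± 0.15, pgl-1 at -1.63 ± 0.15, nos-1 at -1.66 ± 0.17 and xnd-1 at -1.59 ± 0.16 (adjusted p = 0.378 with an estimated correlation, and 0.844 after quantile normalization). Also lower were rrn-3.1 (-4.24 ± 0.45), ule-3 (-3.77 ± 0.47, with another probe set at -0.09) and the pterin gene qdpr-1 (-2.60 ± 0.19). Of 30 cell division genes 13 were lower, led by the Aurora kinase genes air-1 (-1.81 ± 0.24) and air-2 (-1.37 ± 0.16), cyb-2.2 (-1.52 ± 0.20) and rnr-1 (-1.51 ± 0.19), with adjusted p = 0.182 with an estimated correlation. Of 44 early zygotic genes 9 were lower, among them the skn-1-dependent genes sdz-38 (-1.67 ± 0.20), sdz-1 (-1.59 ± 0.19) and sdz-21 (-1.22 ± 0.16) and the T-box gene tbx-33 (-1.29 ± 0.20), with adjusted p = 0.118 with an estimated correlation. The 32 sdz genes alone had 6 lower (adjusted p = 0.190 with an estimated correlation). In all 1621 probe sets were called, 83 higher and 1538 lower.

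Early pie-1 embryos had lower levels of 17 of the 29 maternal genes, with the oocyte gene oma-2 at -2.48 ± 0.27, the eggshell gene cbd-1 at -2.16 ± 0.27 and the Pumilio gene puf-5 at -2.06 ± 0.24 beside pie-1 (adjusted p = 0.00738 with an estimated correlation). Early pie-1/pal-1 embryos also had 17 lower, with oma-2 at -2.44 ± 0.24, cey-2 at -2.31 ± 0.25 and puf-5 at -2.16 ± 0.22 (adjusted p = 0.0262 with an estimated correlation). Each genotype had 8 of 28 germline genes lower: cgh-1 by -2.19 ± 0.15 and -2.33 ± 0.14, nos-1 by -1.92 ± 0.17 and -2.04 ± 0.16, xnd-1 by -1.51 ± 0.16 and -1.70 ± 0.15, and pgl-1 by -1.32 ± 0.15 and -1.54 ± 0.14 (adjusted p = 0.0551 with an estimated correlation for both). The RNase H gene rnh-1.3 was higher by 2.91 ± 0.30 and 3.21 ± 0.27, cest-26 by 1.63 ± 0.31 and 1.83 ± 0.29, and Y111B2A.2 by 1.59 ± 0.24 and 1.57 ± 0.22. The level of hsp-1 was lower by -2.38 ± 0.29 and -2.49 ± 0.27, rrn-3.1 by -3.70 ± 0.45 and -4.82 ± 0.42, and ule-3 by -3.04 ± 0.47 and -4.10 ± 0.43, although the other ule-3 probe set gave 0.09 in each. The nucleoporin gene npp-7 (1.39 ± 0.22, with another probe set at -0.14) and ND4 (1.37 ± 0.30) were higher in pie-1, and F59C12.4 (1.57 ± 0.19) and gtf-2H5 (1.57 ± 0.21) in pie-1/pal-1 embryos. Of 62 ribosomal protein genes 7 were higher in pie-1 embryos, rpl-38 by 1.36 ± 0.23, rpl-41.1 by 1.25 ± 0.18 and rpl-27 by 1.10 ± 0.16 (adjusted p = 0.377 with an estimated correlation). In pie-1/pal-1 embryos that list had 1 higher and 2 lower and was shifted down (adjusted p = 0.832 with an estimated correlation), a direction that turned under quantile normalization (0.966). In all 577 probe sets were called in pie-1 embryos (43 higher, 534 lower) and 884 in pie-1/pal-1 embryos (31 higher, 853 lower).

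The genes cgh-1, hsp-1 and qdpr-1 alternated in N2 between lettered and numbered times, and rnh-1.3 in N2 measured 3.14, 4.49, 3.17 and 4.84 at 0, 23, 41 and 53 min. Over 23 min alone, the early time with numbered N2 arrays, the call of cgh-1 in pie-1/pal-1 ended (-0.96). The early median changes of probe sets with a mean of at least 5 were -0.516, -0.196 and -0.298 in mex-3/skn-1, pie-1 and pie-1/pal-1. The shares of higher calls were 44%, 40.9% and 34% after quantile normalization and 62.4%, 36.3% and 41.8% after centring on those probe sets, against 5.1%, 7.5% and 3.5% as deposited. The counts were 697, 328 and 424 after quantile normalization and 832, 353 and 469 after that centring. In settings chosen after seeing the data they were 904, 372 and 569 with the GAPDH term, 3095 in mex-3/skn-1 and 1594 in pie-1 at the numbered N2 time, and 1032 in mex-3/skn-1 over the lettered N2 times.

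**Figure D4:**
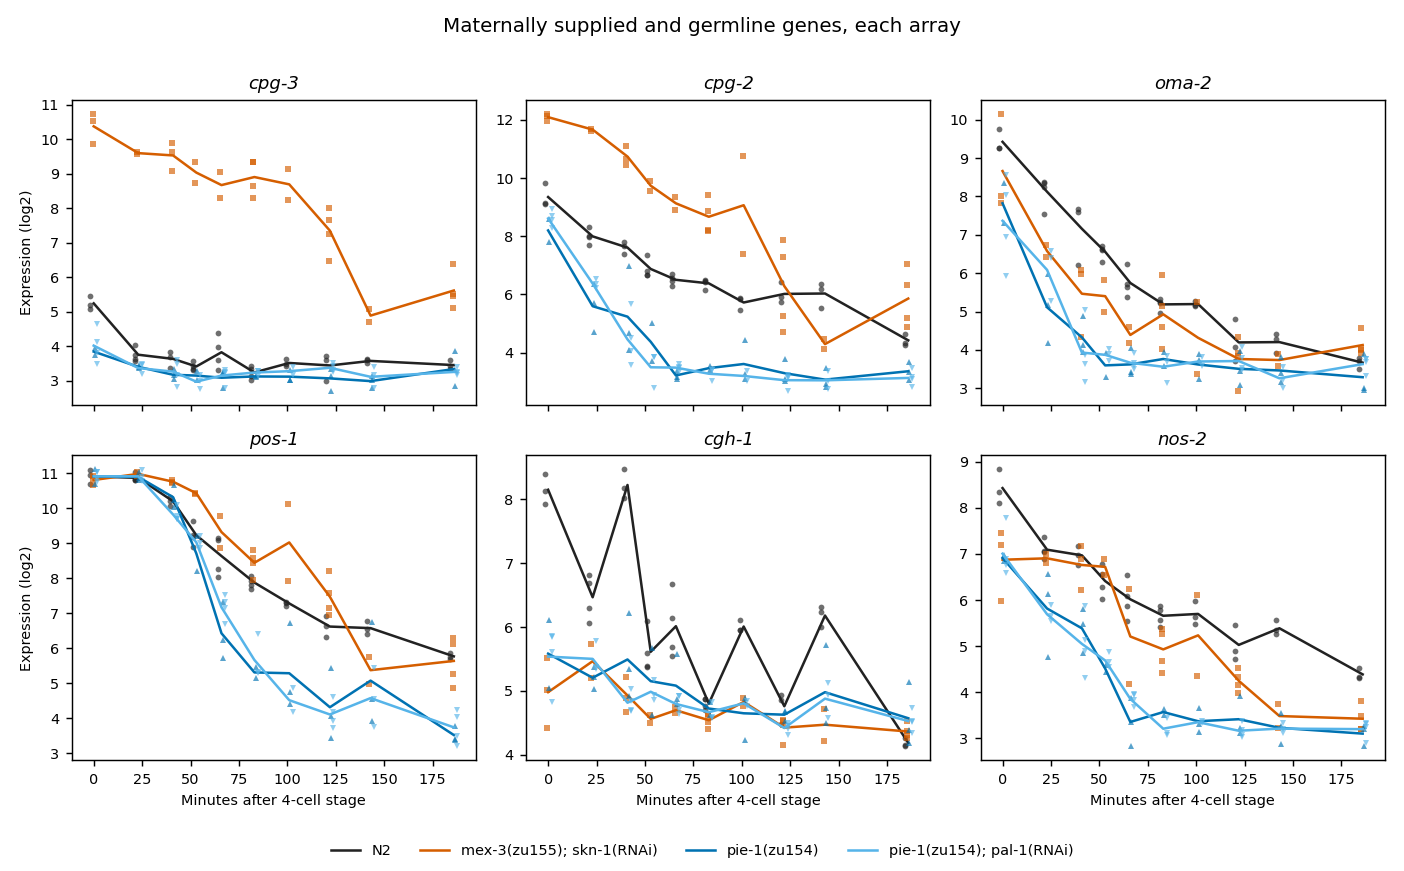
Mean expression (log2) of cpg-3, cpg-2, oma-2, pos-1, cgh-1 and nos-2 against minutes after the 4-cell stage, with a line per genotype and points for arrays. At 0 min cpg-3 stood at 10.37 in mex-3/skn-1 embryos and 5.25 in N2, and cgh-1 in N2 zigzags between 8.15, 6.47, 8.23 and 5.61 over the first 4 time points.

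Whether the genotypes differed in how expression changed from the early to the late window was tested as an interaction. In mex-3/skn-1 embryos ceh-43 (-4.58 ± 0.23), T19B10.2 (-4.59 ± 0.28), C29F7.2 (-4.21 ± 0.24), nuc-1 (-4.09 ± 0.27) and ugt-23 (-3.82 ± 0.27) gained less than in N2. The neuronal list had 6 members lower, with ceh-36 at -3.37 ± 0.19, lin-32 at -1.90 ± 0.20 and unc-130 at -1.67 ± 0.15 (adjusted p = 0.000574 with an estimated correlation). The endoderm list had 4 lower, with dve-1 at -2.81 ± 0.24 and elt-7 at -1.57 ± 0.18 (adjusted p = 0.00296 with an estimated correlation), and the EMS and MS list had 3 lower and 1 higher, with pha-4 at -3.82 ± 0.22, ceh-51 at -2.01 ± 0.24 and sdz-38 at 1.33 ± 0.26 (adjusted p = 0.00738 with an estimated correlation). Over the numbered N2 times the EMS and MS call ended (0.0613). The genes mex-3 (3.44 ± 0.47), ZC239.20 (2.47 ± 0.21), F14H3.6 (2.26 ± 0.32), skr-15 (2.2 ± 0.28) and qdpr-1 (2.14 ± 0.25) had higher interaction values, as did scrt-1 (1.59 ± 0.21) and tbx-9 (1.23 ± 0.26) among the PAL-1 downstream genes (camera adjusted p = 0.117).

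In pie-1 and pie-1/pal-1 embryos the PAL-1 downstream genes gained less than in N2, 8 of 13 in pie-1 (9 adjusted over the list alone) and 9 of 13 in pie-1/pal-1 embryos. The list was partly chosen by the study on these samples, and adjusted p = 3.35e-06 with an estimated correlation in each. In pie-1 embryos hlh-1 measured -1.92 ± 0.21, unc-120 -1.50 ± 0.26, nhr-25 -1.19 ± 0.21 and lin-26 -1.13 ± 0.21, and in pie-1/pal-1 embryos hlh-1 measured -1.81 ± 0.20, elt-1 -1.73 ± 0.33, unc-120 -1.58 ± 0.24 and scrt-1 -1.06 ± 0.19, which was -0.99 without the pie-1/pal-1 array at 101 min, replicate 2. The epidermal list was lower too, with sqt-3 at -1.44 ± 0.20 and -1.41 ± 0.19 (adjusted p = 0.00447 and 0.000898 with an estimated correlation). Of 7 Hox genes the posterior gene nob-1 measured -1.02 ± 0.26 in pie-1/pal-1 embryos (list adjusted p = 0.0269 with an estimated correlation), with another nob-1 probe set near the floor at 0.04, and each of 12 arrays left out singly ended the nob-1 call. Lowest were spp-10 (-4.53 ± 0.24 and -4.90 ± 0.23), aass-1 (-3.61 ± 0.23 and -3.71 ± 0.22), mfsc-1 (-2.87 ± 0.21 and -2.75 ± 0.20) and rnh-1.3 (-2.69 ± 0.39 and -3.03 ± 0.37), with dhp-2 (-3.06 ± 0.23) in pie-1 and T22B7.3 (-2.92 ± 0.20) in pie-1/pal-1 embryos. Highest in both was pie-1 itself (3.15 ± 0.19 and 3.17 ± 0.18), whose N2 level falls from early to late. In pie-1 embryos oops-1 (1.73 ± 0.16), oma-2 (1.64 ± 0.35), H11L12.1 (1.62 ± 0.23) and cgh-1 (1.61 ± 0.20) followed, and in pie-1/pal-1 embryos cey-2 (1.89 ± 0.33), qdpr-1 (1.76 ± 0.24), nlp-31 (1.74 ± 0.30) and F14H3.6 (1.74 ± 0.31).

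The interaction was called for 834 probe sets in mex-3/skn-1 (331 higher, 503 lower), 200 in pie-1 (71 and 129) and 263 in pie-1/pal-1 embryos (151 of them higher). In mex-3/skn-1 the direction depended on the N2 arrays used: 1628 were higher and 441 lower over the numbered N2 times, and 157 and 977 over the lettered ones. With a fixed replicate block 463 were higher and 458 lower. The share of higher values was 35.5% in pie-1 and 57.4% in pie-1/pal-1 as deposited but 62.1% and 38.3% after centring on brighter probe sets, and in pie-1/pal-1 it was 41.7% after quantile normalization.

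Counted at each time point, probe sets called against N2 ranged from 583 at 186 min to 3647 at 143 min in mex-3/skn-1, from 170 at 83 min to 1967 at 66 min in pie-1, and from 433 at 101 min to 1749 at 41 min in pie-1/pal-1 embryos. The count at 143 min in mex-3/skn-1 rests on 2 arrays, replicates 2 and 5, whose root mean square residuals, 0.569 each, were the largest of all arrays and whose array weights, 0.215 each, were the lowest. The 3 pie-1 arrays at 66 min had residuals from 0.385 to 0.410, against a median of 0.251 over all arrays. Replicate 1 of these (0.410) and replicate 1 of pie-1/pal-1 at 41 min (0.433) were among the 9 arrays far from their groups. Against N2 at 0 min, N2 itself had 792 called at 23 min and 3968 at 143 min, and 8833 probe sets passed limma's F test over the 9 later time points.

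**Figure D5:**
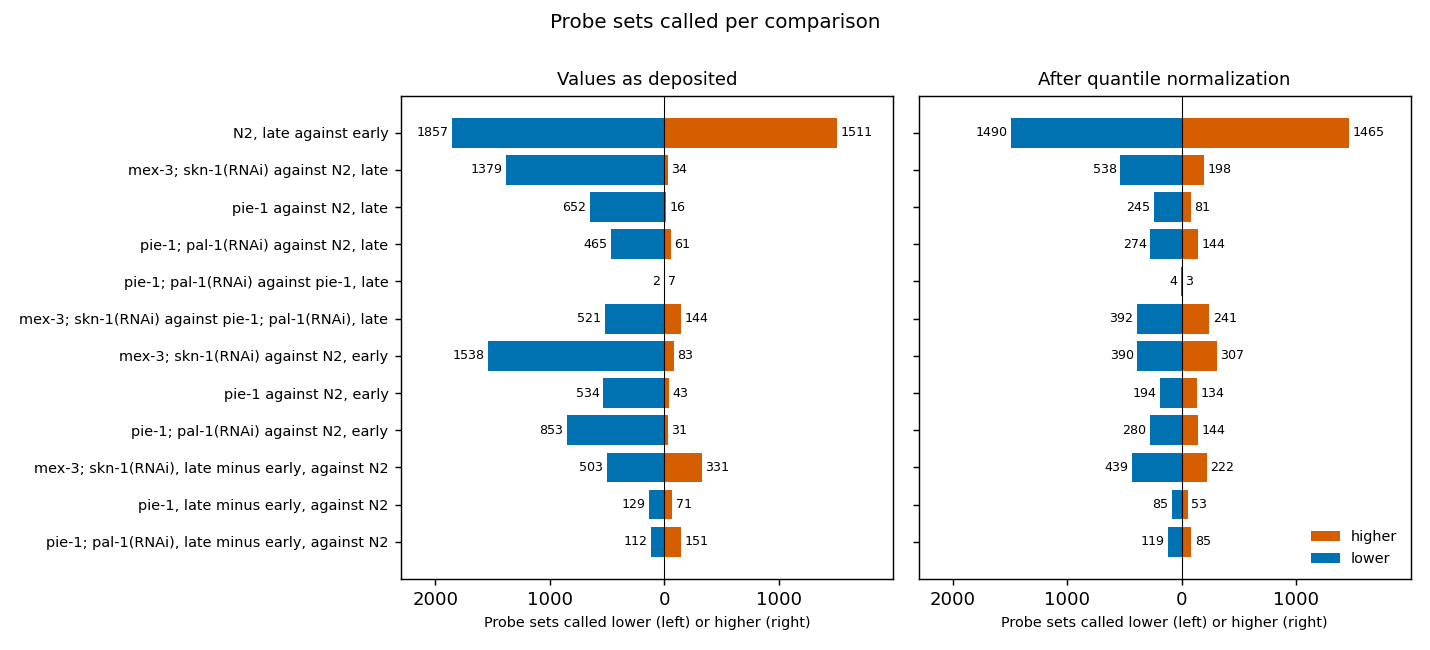
Number of probe sets called in each comparison, with bars to the left for lower and to the right for higher values, as deposited and after quantile normalization. Late mex-3/skn-1 against N2 had 34 higher and 1379 lower as deposited, and 198 and 538 after quantile normalization.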

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

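Of the tests in this part, those on the general shift of the mutant arrays and on pie-1 arrays holding pal-1(RNAi) embryos were chosen only after the result was seen.

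Within groups of at least 4 arrays, 48 tests of the targeted genes found 3 arrays far from the others, where chance gives about 5%. They are all mex-3/skn-1 arrays. At 186 min pie-1 was 3.97 in replicate 5 and 3.68 to 3.72 in the others, and mex-3 was 6.36 in replicate 7 and 3.63 to 3.90 in the others. At 122 min skn-1 was 3.71 in replicate 1 and 4.31 to 4.41 in the others. The 12 groups tested held no pie-1 group, and smaller groups were not tested. Among these, pie-1/pal-1 at 143 min, replicate 1, had mex-3 at 9.46, against 3.36 and 4.49 in the other arrays. The other mex-3 probe set did not show these high values. By that probe set no late pie-1/pal-1 array lay above 4.30 and no late mex-3/skn-1 array above 3.88.

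The change from the early to the late window differed from that of N2 by the interaction test in every mutant, with 834 probe sets called in mex-3/skn-1, 200 in pie-1 and 263 in pie-1/pal-1 embryos. Of 100 splits of the same arrays, the real one included, 3 gave as many calls for mex-3/skn-1 (highest other 2201), 3 for pie-1 (highest other 621) and 2 for pie-1/pal-1 (highest other 264). Each split swapped genotype labels separately at each time point. It can thus turn a difference between genotypes into a difference of change. Splits with more calls than the real one can arise that way, so these splits do not decide whether chance accounts for the interaction counts. What those splits grouped by was not examined.

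For the other comparisons 1 of 100 splits, the real one, gave as many calls. The highest other split had 411 against 1413 for late mex-3/skn-1, 161 against 668 for late pie-1, 25 against 526 for late pie-1/pal-1, 298 against 665 for mex-3/skn-1 against pie-1/pal-1, and 1583 against 3368 for late against early N2. Early it had 901 against 1621, 59 against 577 and 103 against 884 for the 3 mutants in the same order. Summed over time points it had 7355 against 16585, 3149 against 9293 and 2075 against 10381, and for the F test over N2 times 4432 against 8833. For late pie-1/pal-1 against pie-1 the real count was 9, the highest other 11, and 2 of 100 splits gave as many. Where only the real split gave as many calls, chance spread among single arrays can be excluded as the whole source at that level. The splits moved arrays singly, and replicates may be technical. Chance differences between scan days or embryo collections therefore cannot be excluded, and neither can the batch of a mutant. For late pie-1/pal-1 against pie-1 another split had more calls than the real one, so chance stays open there.

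Calls against N2 were mostly lower in the mutants. A different scale or spread of the arrays may contribute: after quantile normalization the lowest share of higher late calls among the 3 mutants was 24.8%, against 2.4% as deposited, where most calls were still lower. After centring on probe sets with a mean of at least 5 the shares were 59.6% in mex-3/skn-1, 36.9% in pie-1 and 42.5% in pie-1/pal-1, so most mex-3/skn-1 calls were then higher. The direction of the mex-3/skn-1 calls depends on the scaling, and this account stays open. RNA amplification or 3' bias may contribute too, since the GAPDH difference as a term left at most 0.6 of the late calls, but GAPDH differs with genotype and the term removes part of any genotype effect. The absence of cell types that appear late in N2 would predict few of the late lower probe sets to be lower early. The shares also lower early were 42.3% in mex-3/skn-1, 32.1% in pie-1 and 47.5% in pie-1/pal-1, between the limits set beforehand for and against, where 6.8%, 2.4% and 3.8% of all probe sets were lower early. Part of the late calls were thus present early, and that account stays open for the rest. Scan day, chip lot and genotype cannot be told apart here.

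Genes downstream of PAL-1 were lower than in N2 in both pie-1 and pie-1/pal-1 embryos, comparisons that share the N2 arrays. The list median minus the median of probe sets with a mean of at least 5 was -0.8 in each genotype, so the list members moved apart from those probe sets. The list was partly chosen by the study on these samples. The gap could follow from that choice, and it is no independent evidence that the members fell. It therefore does not decide whether a general shift of the mutant arrays was the whole cause. Whether pie-1 arrays held pal-1(RNAi) embryos stays open for the late arrays. The late pal-1 medians of pie-1 minus pie-1/pal-1 arrays were -0.08, -0.22 and 0.25 for its 3 probe sets, and the largest, 0.25, lies far below the difference of at least 1 that would argue against it. The early medians were 2.65, 1.2 and 2.77 higher in pie-1 arrays, which argues against it for early arrays only, and the pie-1 array at 53 min, replicate 3, had pal-1 at 12.49, above the highest pie-1/pal-1 array (12.21). Whether the loss of PIE-1 function accounts for the lower levels of these genes was not tested here, and a batch difference from N2 stays open too.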

How the results depend on the processing

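Scan day as a fixed block, the settings on chip lot, centring on probe sets with a mean of at least 5, the GAPDH term, leaving out arrays far from their group, the settings that follow N2 naming, and those on rehybridised arrays and conflicting notes were chosen only after the data were seen. Other scalings of the counts over time points were also chosen then. The planned pseudocounts were not run, since the table holds log2 values. Where a result changed, the cause was not tested unless stated.

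Under quantile normalization the late counts were 736 in mex-3/skn-1 and 326 in pie-1, the early counts 697, 328 and 424 in mex-3/skn-1, pie-1 and pie-1/pal-1, and the sum over pie-1 time points 5290 against 9293. Centring on brighter probe sets gave 822 and 312 late, 832, 353 and 469 early, and 30275 against 16585 over mex-3/skn-1 time points. The GAPDH term gave 851, 341 and 245 late and 904, 372 and 569 early. Without a fold minimum, which by construction admits smaller changes, counts were 7697 for N2, 8685, 9307 and 7201 late, 549 for pie-1/pal-1 against pie-1, 4216 for mex-3/skn-1 against pie-1/pal-1, 9041, 5348 and 8956 early, and 2682, 924 and 1432 for the changes. Narrow windows gave 19 for pie-1/pal-1 against pie-1, and leaving out 1 array gave 6 to 14.

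The limit for arrays far from their group, a root mean square residual over 0.6, left out no array and was lowered to 0.4 after the residuals were seen. It then left out 9 arrays, among them both mex-3/skn-1 arrays at 143 min, so the late window lost that time in every genotype. This setting gave 934 late calls in mex-3/skn-1, 343 in pie-1/pal-1, and 406 for the change in pie-1/pal-1. Over times with numbered N2 arrays counts were 780 late and 3095 early in mex-3/skn-1, 1594 early in pie-1, and 2069 (78.7% higher, against 39.7% of 834 in the report) and 348 for their changes. Over times with lettered N2 arrays they were 2487, 1024 and 818 late in mex-3/skn-1, pie-1 and pie-1/pal-1, and 1032 early in mex-3/skn-1, and its change had 1134 calls, 13.8% of them higher. Fewer time points enter these settings.

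Few single genes and lists changed direction with a call on either side. The list leaves out sign differences where neither value was called, such as late pal-1 in pie-1/pal-1 embryos (0.20, with other probe sets at -0.77 and -0.72). The gene dpy-17 in the mex-3/skn-1 change was 0.19 in narrow windows, sqt-3 in mex-3/skn-1 against pie-1/pal-1 was -0.02 within chip lot 2, rnr-1 in the mex-3/skn-1 change was 0.03 over numbered times, and list tests changed direction in 7 cases, given with their adjusted p. Under quantile normalization these were the ribosomal list in early pie-1/pal-1 (0.966) and in the mex-3/skn-1 change (0.0435). Over numbered times they were that list in late (0.0102) and early pie-1/pal-1 (0.299) and its change (2.18e-05), and the cell division list in the changes of mex-3/skn-1 (0.000998) and pie-1 (0.691). Other probe sets of the same gene reversed in late pie-1 for rab-11.1 (-0.28), zfp-3 (-0.39, -0.41 and -0.45), swsn-1 (-0.20) and spp-10 (0.01), and in late pie-1/pal-1 for rab-11.1 (-0.18), spp-10 (0.08) and ule-3 (0.11). They did for tln-1 in pie-1/pal-1 against pie-1 (-0.10, -0.04 and -0.19), unc-44 in mex-3/skn-1 against pie-1/pal-1 (0.06, 0.03 and 0.03), ztf-11 (0.07) and pal-1 (-1.33) in early mex-3/skn-1, npp-7 (-0.14) and ule-3 (0.09) in early pie-1, ule-3 (0.09) in early pie-1/pal-1, and nob-1 in the changes of pie-1 (0.06) and pie-1/pal-1 (0.04).

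Of 757 gene results, quantile normalization kept 667 on their side of the threshold, centring on brighter probe sets 660, the array median 752, the GAPDH term 699, array weights 737, and an adjusted p of 0.01 kept 754. Of the 216 list tests, 54 of 77 calls ended with an estimated correlation, and quantile normalization ended 16, added 19 and reversed 2.

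Replicate numbers are not stated to pair arrays. Arrays with the same number correlated by 0.129 on average over 303 pairs of the same genotype at other times, and by -0.016 over 74 pairs of other genotypes at the same time. As a random replicate block the correlation was 0.0973, and early pie-1/pal-1 had 1236 calls with a fixed replicate block. No block moved a count of a comparison by over 1.5 times. With scan day as a fixed block 3126 probe sets were called in N2, and low signal limits genes near the floor, such as skn-1, lower in early mex-3/skn-1 by 1 of its 3 probe sets.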

Other observations

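The early zygotic genes pes-10 and vet-6 came on and went off again within the course. In N2 pes-10 rose from 3.23 at 0 min to 8.94 at 66 min and was back at 3.11 at 186 min, and in mex-3/skn-1 embryos it reached 7.87. The level of vet-6 in N2 was 3.25 at 0 min and 3.63 at 186 min. Between these it was 10.33 at 83 min and 8.49 at 143 min, against 8.34 and 4.42 in mex-3/skn-1, 9.78 and 6.42 in pie-1, and 9.57 and 5.07 in pie-1/pal-1 embryos. The endoderm GATA gene end-3 stood at 4.57 in N2 at 41 min and at 3.17 in mex-3/skn-1 embryos. The Hox gene ceh-13 reached 6.80 in N2, 6.48 in pie-1 and 7.04 in pie-1/pal-1 embryos and at most 4.13 in mex-3/skn-1 embryos. At 186 min the posterior Hox gene nob-1 was 6.30 in N2, 7.53 in mex-3/skn-1, 4.19 in pie-1 and 4.74 in pie-1/pal-1 embryos. These courses were chosen after their values were seen, and no tests at single times are given for them.

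Other lists gave fewer changes. Of 7 Hox genes ceh-13 (3.08 ± 0.18) and nob-1 (2.55 ± 0.19) rose in N2 (adjusted p = 0.105 with an estimated correlation), and another nob-1 probe set near the floor gave 0.16. Of 8 Notch genes lin-12 rose by 2.18 ± 0.19 and apx-1 fell by 1.29 in N2 (camera adjusted p = 0.970), and lin-12 and ref-1 were lower by -1.03 ± 0.19 and -1.03 ± 0.16 in late mex-3/skn-1 embryos (adjusted p = 0.226 with an estimated correlation). Both of those calls ended under quantile normalization (-0.52 each). Leaving out single arrays ended the call of lin-12 for 5 arrays, with -0.87 without the mex-3/skn-1 array at 143 min, replicate 5, and that of ref-1 for 4, with -0.91 without the mex-3/skn-1 array at 101 min, replicate 4. Of 15 pharynx genes pha-4 and eya-1 (3.18 ± 0.17) rose in N2 (camera adjusted p = 0.148). Of 14 stress genes nhr-57 (1.39 ± 0.13) and hsp-3 (1.75 ± 0.33) rose in N2 (camera adjusted p = 0.809). The N2 level of hsp-3 went up and down between neighbouring times, with 6.37, 8.06, 6.92 and 8.61 at 0, 23, 41 and 53 min. Of 160 collagen and cuticle genes 8 rose and 1 fell in N2, dpy-17 by 3.46 ± 0.26, dpy-14 by 2.92 ± 0.19 and bli-4 by -2.60 ± 0.14, with another bli-4 probe set at 0.00 (adjusted p = 0.671 with an estimated correlation). Of 44 early zygotic genes 14 rose and 7 fell in N2 (camera adjusted p = 0.629), sdz-28 by 3.92 ± 0.17 and sdz-37 by -1.73 ± 0.13, and of the 32 sdz genes 10 rose and 5 fell (camera adjusted p = 0.328). Of 42 genes of adult soma and sperm limma called 0 in N2, with 6 at an unadjusted p under 0.05 and values from -0.22 to 0.41 (camera adjusted p = 0.534). Of 27 body muscle genes 6 rose in N2 (adjusted p = 0.190 with an estimated correlation), dim-1 by 1.51 ± 0.12 among them.

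The tests of alternate N2 time points and the choice of alternating genes were made only after the values were seen. The level of 158 probe sets alternated in N2 between the times with lettered and those with numbered replicates. If replicate naming marked separate sets, the lettered and numbered arrays at 66 min, 2 of each, would differ with the same signs. They did so in 61.4% of the 158, against 51.9% and 50% in the other 2 ways to pair those arrays, which decides nothing with 4 arrays. At 66 min 97.5% of the 158 lay off the mean of 53 and 83 min with the sign of the lettered times, 99.4% in the lettered arrays and 88% in the numbered arrays alone. This may mean that the arrays of every other time point, 66 min included, form separate sets however they are named, a candidate explanation with the limit that 53 and 83 min also entered the choice of the probe sets. No biological explanation was tested.

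The notes of 2 arrays give 143 min where the label gives another time. Over 7111 probe sets, the correlation with other arrays of the noted time minus that with arrays of the labelled time was -0.0702 for mex-3/skn-1 at 186 min, replicate 5, which favours the label, although the 2 reference arrays at 143 min stand apart from each other. It was 0.0197 for pie-1/pal-1 at 122 min, replicate 5, which favours the note. These correlations run across genes, which are not independent replicates.

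Mutant arrays matched N2 arrays of their own time best in most cases. The median offset was 0 time points in mex-3/skn-1, 0 in pie-1 and 0 in pie-1/pal-1 embryos, with 96.4%, 96.3% and 91.2% of arrays within 1 time point, and the arrays off their own time matched later N2 times in all 8 such pie-1 and all 15 such pie-1/pal-1 arrays. In mex-3/skn-1 and pie-1 embryos this argues against an offset of a whole time point over the course. Arrays at 186 min, 4 of them pie-1/pal-1, could not match a later N2 time. With 15 later matches the median of pie-1/pal-1 arrays therefore does not decide, and a later stage stays open there. A later stage at single times stays open too, such as 41 min, where 3 of 4 pie-1/pal-1 arrays matched N2 at 66 min. The match also depends on the N2 arrays, since N2 at 23 min was the best match of 1 mutant array and N2 at 53 min of 0.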
